A study of Lupinus albus with 12 samples.

How the data were processed

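Transcript abundance was measured by RNA sequencing in leaves and roots of white lupin (Lupinus albus), a legume that forms clusters of short lateral rootlets, called proteoid or cluster roots, when phosphorus is scarce. The 12 libraries fall into 4 groups of 3 biological replicates: roots and leaves, each with sufficient or deficient phosphorus. Per the labels' protocols, sufficient plants received 1 mM calcium phosphate and deficient plants 1 mM calcium sulfate in its place, and tissue was harvested 14 days after emergence. The labels name the deficient root samples proteoid roots and the sufficient ones roots, so the root comparison differs in root type as well as in supply. Growth is described as in soil in one field of the labels and with nutrient solutions in another.

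Per the labels' protocols, poly-A RNA was sequenced for 76 cycles on an Illumina Genome Analyzer, and reads were filtered for quality, homopolymers and size. Replicate 1 libraries were run 1 per lane without barcodes, and those of replicates 2 and 3 were barcoded and run 2 per lane, so sequencing format differs between replicates and not between groups. Per the submitters' processing notes, Bowtie was used, with neither version nor role given. The sequences of the deposited table carry identifiers that begin with LAGI. How reads were counted and how reads that match several sequences were assigned are not given in the sources used here. Near-identical copies and isoforms carry the same description, and how the reads were divided between them is uncertain.

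The deposited values were taken to be RPKM (reads scaled for sequence length and library size), a unit that the labels and deposited files used here do not name. They have 1 decimal, their sums per library run from 802814.9 to 1178058.3, and the smallest values above 0 depend on the number in the sequence identifier. This order was taken to follow length from these values alone, since no lengths were given. The table holds 125535 sequences and 2 empty columns, and 125821 sequences have a deposited annotation with the best hit to Arabidopsis or soybean proteins. The reference table of RefSeq gene names (assembly CNRS_Lalb_1.0) shares no identifiers with the LAGI sequences, so names come from the deposited annotation alone and no genome positions are given. No read counts were used, and the depth of each library is unknown. The commonest low value of the sequences numbered last, taken to be the shortest and to stand for few reads, was 0.3 to 0.5 RPKM in all 12 libraries. No 2 libraries held identical values.

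Groups, comparisons, tests, filter, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. A count-based test had been fixed for the case of counts. Because the values were taken to be RPKM, the form fixed for normalized values was used and the count-based tests were not run. Sequences at 1 RPKM or more in at least 3 libraries were kept (87081, 69.37%), of which 59084 (67.8%) have an informative description. Values were transformed to log2(RPKM + 0.5) with no further scaling, so a fold change is on that scale and understates the change of low sequences. Limma (version 3.58.1 in R 4.3.3) with an intensity trend was fitted to the 4 group means over all 12 libraries, which share a single estimate of the spread. P-values were adjusted by Benjamini and Hochberg over all sequences tested, and a call is an adjusted p below 0.05. The 5 contrasts were deficient minus sufficient in roots and in leaves, the difference of these responses, and root minus leaf at each supply. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

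Membership in 27 gene lists followed patterns in the descriptions, and the 26 lists with at least 5 tested members were tested with camera from limma, with a preset correlation of 0.01 and adjustment over the lists of a contrast. Camera compares a list with all other sequences, so its direction is relative to them. Genes named for the root and leaf responses are the 8 largest rises and 8 largest falls among calls whose groups do not overlap, with a mean of at least 5 RPKM in the higher group and an informative description, 1 per description. To these were added the 2 members with the smallest adjusted p of each of 8 core lists, called or not. For the difference of responses and the tissue contrasts the 5 largest in each direction were taken, and for other lists the 2 members with the smallest p could be named. Any other gene named was chosen after its values were seen.

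The procedure was tested on simulated data with 200 of 87081 sequences changed. The changed sequences were drawn only from those with a mean of at least 5 RPKM over the 12 libraries. The recovery of lower sequences was therefore not tested. In the simulated root response it recovered 0% of 67 changed 2-fold, 25.4% of 67 changed 4-fold and 86.4% of 66 changed 8-fold. For the leaf response these shares were 0%, 31.3% and 90.9%. False calls were 7 of 81 in the root simulation and 11 of 92 in the leaf simulation, and the unchanged tissue gave 0 calls with limma. Camera called the changed list of 40 members in both and 0 of 20 random lists. Each simulated sequence had independent noise, with no correlation within lists, no outlying library and no replicate effects. The random lists therefore do not test the preset correlation. In the real lists the estimated correlation ran from 0.09 to 0.764.

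Whether replicate numbers pair libraries was checked from the deviations of each library from its group mean. Same-numbered sufficient and deficient libraries correlated across sequences at 0.751, 0.399 and 0.644 in roots and at 0.237, 0.237 and 0.126 in leaves. In leaves each different-number correlation was lower (-0.301 to 0.106). In roots sufficient 2 with deficient 3 and sufficient 3 with deficient 2 stood at 0.441 and 0.472, so only replicate 1 stands apart there and replicates 2 and 3 are not shown to pair. The block within each tissue treats all numbers as pairs. Between a root and a leaf library the same-number correlations ran from -0.223 to 0.34 and those of different numbers from -0.32 to 0.265, so numbers were not taken to pair libraries across tissues. The alternatives were quantile normalization, no filter, pseudocounts of 0.1 and 1, the replicate number as a block, lane format as a covariate, each library left out, the barcoded libraries only, values summed per description and, for the phosphorus responses, the libraries of 1 tissue only. Those added after the data were seen were median-of-ratios scaling, array weights, a block within each tissue, clock genes as a covariate, adapted list patterns and combinations of these.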

Results

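The data are 12 libraries of white lupin, 3 from each of roots and leaves with sufficient or deficient phosphorus. Tissue separated them most, with the first principal component carrying 73.9% of the variance and the next 3 components 8%, 7.2% and 3.1%. The deficient leaf library of replicate 3 stood apart: its 20 largest sequences held 70.91% of its summed RPKM, against 12.51% to 17.98% in the other 5 leaf libraries, and its median tested sequence stood at 0.9 RPKM against 2.1 to 2.6. Sums of RPKM ran from 802814.9 to 947804.4 in the other 11 libraries and reached 1178058.3 in that one. The depth of the libraries is unknown. Morning clock genes (LHY and CCA1, 35 sequences) minus evening clock genes (TOC1, GI and APRR5, 40 sequences) differed within groups by up to 4.1 on the log2 scale. This difference was 1.45, -2.57 and -2.65 in sufficient leaves and 3.08, 1.83 and 1.58 in deficient leaves, for replicates 1 to 3. In roots it was -0.09, -1.88 and -2.09 with sufficient and 1.0, 0.0 and -0.77 with deficient phosphorus.

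The root comparison asks which transcripts differ between deficient roots, sampled as proteoid roots, and sufficient roots. The largest rise was in PAP10 (LAGI01_35427), a secreted purple acid phosphatase that frees phosphate from organic compounds, from 0.60 ± 0.26 to 177.83 ± 27.97 RPKM (mean ± SD, n = 3; log2 fold change 7.36, SE 0.362, limma adjusted p = 2.98e-08). The phosphate transporter PHT5 (LAGI01_79525) rose from 2.73 ± 1.8 to 86.97 ± 17.48 RPKM (log2 4.92, SE 0.397, limma adjusted p = 3.96e-06). Not all copies were called: 4 of 9 tested sequences described as PAP10 were higher (median log2 change of the 9, -0.16). For PHT5 it was 3 of 8 (median 0.59). LPR1 (LAGI01_52976), a multicopper oxidase known from the root growth response to low phosphate, rose from 9.27 ± 3.04 to 224.83 ± 66.91 RPKM (log2 4.54, SE 0.363, limma adjusted p = 3.83e-06). FRD3 (LAGI01_21605), a citrate exporter that moves iron into the xylem, rose from 17.13 ± 12.29 to 320.17 ± 79.85 RPKM (log2 4.55, SE 0.558, limma adjusted p = 6.84e-04). PHO2 (LAGI01_2053), a ubiquitin-conjugating enzyme that limits phosphate uptake in sufficient plants, fell from 27.17 ± 3.64 to 3.03 ± 1.81 RPKM (log2 -3.08, SE 0.453, limma adjusted p = 0.00394).

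Other large rises in deficient roots were in a putative nodulin (LAGI01_56202, log2 5.02 ± 0.442 SE), a putative peroxidase (LAGI01_45494, 4.75 ± 0.291), a phosphatase (LAGI01_58330, 4.60 ± 0.694) and ALDH11A3 (LAGI01_24999, 4.48 ± 0.521). Their limma adjusted p was 1.16e-05, 1.65e-07, 0.00515 and 3.98e-04, and ALDH11A3 is the non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase. Among transcripts that fell were AHB2 (LAGI01_67056), a non-symbiotic haemoglobin, at -2.38 ± 0.399, a pectinesterase of cell wall pectin (LAGI01_81839) at -2.12 ± 0.315 and the beta-glucosidase BGLU32 (LAGI01_66998) at -1.98 ± 0.324, with limma adjusted p of 0.0112, 0.00443 and 0.00923. The glucosyltransferases AtUGT85A2 (LAGI01_55919, log2 -2.16 ± 0.398) and AtUGT85A3 (LAGI01_73516, -1.97 ± 0.377), a myb transcription factor (LAGI01_50728, -2.05 ± 0.416) and the receptor-like kinase LRR XI-23 (LAGI01_14255, -1.56 ± 0.308) also passed, at limma adjusted p of 0.024, 0.0321, 0.0491 and 0.0394. Their calls were kept in 18, 10, 9 and 11 of 26 alternatives. The pectinesterase went from 44.37 ± 5.22 to 9.9 ± 2.0 RPKM.

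**Figure D1:**
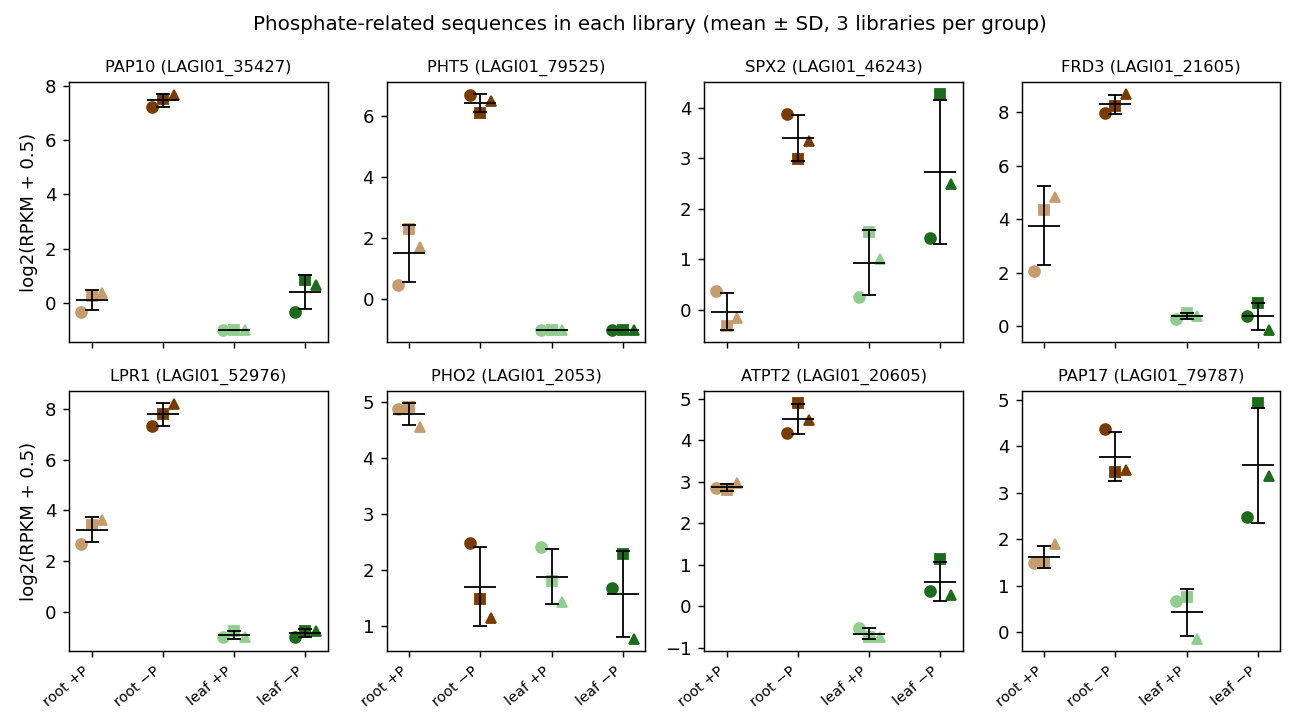
Log2(RPKM + 0.5) of 8 sequences in each of the 12 libraries, by tissue and phosphorus supply; circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean ± SD of the log2 values of each group (n = 3). PAP10 rose by 7.36 in roots and PAP17 by 3.16 in leaves on this scale, and PHO2 fell by 3.08 in roots.

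Of 14 tested sequences of SPX proteins, which bind inositol phosphates and report phosphate status, 10 were higher in roots and 0 lower with limma. The median log2 change was 2.76, and 13 were higher adjusted over the list alone. Among all tested sequences 7 of 9 described as SPX2 and 3 of 4 described as SPX3 rose, so the list may rest on copies of few genes. Camera gave an adjusted p of 4.9e-45 for this list, and it was the only list also called with the other correlation (adjusted p = 0.0454 with an estimated correlation). With the adapted pattern of 31 SPX sequences the median was 0.09, and that list was not called with an estimated correlation (adjusted p = 0.543). SPX2 (LAGI01_46243) went from 0.50 ± 0.26 to 10.43 ± 3.46 RPKM (log2 3.44, SE 0.555, limma adjusted p = 0.00857) and SPX3 (LAGI01_62170) from 0.37 ± 0.12 to 5.43 ± 1.6 RPKM (2.75, SE 0.44, 0.0081). Of 38 phosphate starvation regulators 8 were lower, all of them among the 14 tested PHO2 sequences (9 lower adjusted over the list alone, median -0.12, camera adjusted p = 3e-09 and adjusted p = 0.815 with an estimated correlation). With adapted patterns 8 of 45 were lower and 2 higher. Further PHO2 copies, LAGI01_2694 and LAGI01_2480, stood at -3.07 ± 0.448 and -3.00 ± 0.437, both with limma adjusted p = 0.00366. Of 43 phosphate transporters 0 passed limma over all sequences, 12 were higher adjusted over the list alone, and the median was 0.74 (camera adjusted p = 1.5e-19, adjusted p = 0.148 with an estimated correlation). ATPT2, a high-affinity transporter, stood at 1.65 ± 0.339 (LAGI01_20605, 6.83 ± 0.42 to 22.97 ± 5.87 RPKM) and 1.83 ± 0.376 (LAGI01_14440), with limma adjusted p of 0.0535 and 0.054. With the replicate block these became 0.0383 and 0.0332, and with the block within each tissue 0.0368 and 0.0304. The list pattern missed PHT5; with patterns adapted to the descriptions after the data were seen, 3 of 51 transporters were higher, all of them PHT5 (15 adjusted over the list alone, camera adjusted p = 1.07e-25, adjusted p = 0.123 with an estimated correlation). Of 6 sequences described as a carbohydrate and phosphate transmembrane transporter 2 also rose (log2 1.80 and 1.97). Both patterns missed these 2.

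Phosphate release and lipid remodelling enzymes rose in part in roots. Of 140 sequences that the pattern for purple acid phosphatases took in 7 were higher (11 adjusted over the list alone), among them a further PAP10 sequence (LAGI01_49867, 0.33 ± 0.12 to 43.3 ± 9.28 RPKM, log2 5.70 ± 0.302, limma adjusted p = 4.92e-08). The median was -0.07 and the mean 0.22, and camera did not call the list (direction higher, adjusted p = 0.186). The pattern also matched phosphatidic acid phosphatases and phytochrome-related proteins, and the adapted pattern without them holds 58. Of these 6 rose, with a median of 0.09 and a mean of 0.71. Camera placed the adapted list higher (camera adjusted p = 8.26e-09, adjusted p = 0.543 with an estimated correlation). Of 118 other phosphate release enzymes 2 were higher (7 adjusted over the list alone, median 0.05, camera adjusted p = 0.0191): the lipid phosphate phosphatase LPP2 (LAGI01_76393, log2 2.00 ± 0.31) and a phosphatidic acid phosphatase (LAGI01_92953, 1.93 ± 0.303), with limma adjusted p of 0.00622 and 0.00678. The adapted pattern drops both and had 0 of 71 called with limma (4 higher adjusted over the list alone, camera adjusted p = 0.00663, adjusted p = 0.913 with an estimated correlation). Membrane lipid remodelling had 7 of 159 higher (41 adjusted over the list alone, median 0.12, camera adjusted p = 2.57e-12), including the glycerophosphodiester phosphodiesterase SRG3 (LAGI01_75880, log2 2.46 ± 0.383, limma adjusted p = 0.00637). For the lists of 118 and 159 the value was adjusted p = 0.956 with an estimated correlation.

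In organic acid metabolism 3 of 268 sequences rose (3 adjusted over the list alone, median 0.10, camera adjusted p = 0.0077). All 3 encode phosphoenolpyruvate carboxylase, which fixes bicarbonate into oxaloacetate: ATPPC1 (LAGI01_66206, 4.7 ± 0.66 to 19.7 ± 6.51 RPKM, log2 1.91 ± 0.32, limma adjusted p = 0.0109) and a pair of ATPPC3 sequences (LAGI01_74442, 1.87 ± 0.36, 0.0336). The list pattern missed malate synthase MLS, of which 4 of 4 sequences rose (log2 3.03 to 3.57). Of 79 MATE and malate channel transporters, which export organic acids and other metabolites, 4 rose (6 adjusted over the list alone, median 0.05, camera adjusted p = 2.79e-04), all named MATE efflux family proteins, with LAGI01_35458 at 2.04 ± 0.346 and LAGI01_19227 at 1.89 ± 0.36 (limma adjusted p of 0.0131 and 0.0309). These MATE calls were kept in 19 and 13 of 26 alternatives, and those of ATPPC1 and ATPPC3 (LAGI01_74442) in 20 and 17. Sucrose breakdown and glycolysis had 3 of 451 higher, all ALDH11A3 (3 adjusted over the list alone, median 0.10, camera adjusted p = 0.00344). Each of these lists was at adjusted p = 0.956 with an estimated correlation. With adapted patterns, which add FRD3 to the MATE transporters, 12 of 91 rose (15 adjusted over the list alone, camera adjusted p = 2.38e-13, adjusted p = 0.543 with an estimated correlation), and 6 of 58 purple acid phosphatases rose (11 adjusted over the list alone, camera adjusted p = 8.26e-09, adjusted p = 0.543 with an estimated correlation). The adapted SPX pattern took in 31 sequences, of which the same number, 10, rose, and its median was 0.09 (camera adjusted p = 4.15e-07, adjusted p = 0.543 with an estimated correlation).

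Iron and metal homeostasis had 10 of 125 higher (15 higher and 5 lower adjusted over the list alone, median 0.14, camera adjusted p = 1.71e-05), led by FRD3 sequences LAGI01_20061 (3.77 ± 1.21 to 67.4 ± 7.73 RPKM) and LAGI01_72004 at log2 4.03 ± 0.315 and 3.95 ± 0.309, both with limma adjusted p = 3.1e-06. Secretory peroxidases and laccases had 12 of 233 higher (18 adjusted over the list alone, camera adjusted p = 0.00434), with a median of 0.01 that turned to -0.01 with median-of-ratios scaling. A further peroxidase, LAGI01_58965, went from 1.3 ± 0.1 to 43.4 ± 3.22 RPKM. Cell wall modification had 7 of 767 higher and 1 lower (14 and 4 adjusted over the list alone), with the expansin-like ATEXLB1 (LAGI01_53994 and LAGI01_53567) at 2.59 ± 0.339 and 2.53 ± 0.357, while the median was -0.21 and camera called the list lower (adjusted p = 8.77e-04). These 3 lists were at adjusted p = 0.956 with an estimated correlation.

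Camera placed 6 more lists lower in deficient roots, none with a sequence that limma called over all sequences. They were phenylpropanoid and flavonoid synthesis (129 members, median -0.29, camera adjusted p = 6.03e-08; 2 lower adjusted over the list alone), the auxin pathway (401, -0.20, 2.48e-05), the ethylene pathway (282, -0.13, 0.00344), the gibberellin pathway (47, -0.21, 0.00344; 1 higher adjusted over the list alone), nitrogen and sulfur uptake (126, -0.13, 0.0104) and defence proteins (276, -0.11, 0.0303). The gibberellin list was at adjusted p = 0.815 with an estimated correlation and the other 5 at adjusted p = 0.956 with an estimated correlation. In these lists PAL4 (LAGI01_68273), the entry enzyme of phenylpropanoid synthesis, stood at -1.62 ± 0.364 and the sulfate transporter SULTR1 (LAGI01_74007) at -1.66 ± 0.393, with limma adjusted p of 0.0903 and 0.124. Cytosolic ribosomal proteins were placed higher (879, median 0.15, camera adjusted p = 0.00875, adjusted p = 0.967 with an estimated correlation). The other 7 tested lists did not pass camera. They were photosynthesis (272, adjusted p = 0.889), the cytokinin pathway (169, 0.442), histones and cell cycle (345, 0.724) and heat shock proteins (744, 0.33), with root tissue markers (159, 0.564), seed storage and late embryogenesis (73, 0.63; median 0.08, mean -0.09) and ribosomal RNA and organelle transcripts (67, 0.248; median 0.14, mean -0.04). Each had 0 limma calls, also adjusted over the list alone. A pair of nodule marker sequences, too few for a list test, stood at -1.66 and -1.51 (limma adjusted p of 0.229 and 0.299).

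In all, limma called 243 of 87081 sequences in the root phosphorus response, 213 higher (87.7%) and 30 lower, all changed at least 2-fold (3756 at an unadjusted p below 0.05). They include 183 with an informative description under 79 names. Among the barcoded libraries alone the count was 442 (237 higher, 205 lower), and PAP10 stood at 7.27 there and at 7.53 between the 2 replicate 1 libraries, which allow no test. The count fell to 106 with a pseudocount of 0.1, 87 with root libraries only, 58 with values summed per description and 113 without sufficient root replicate 2. The block within each tissue gave 565 calls (400 higher, 165 lower), and with the clock gene difference as a covariate 228 were called, 187 of them shared. The clock gene difference was higher in the deficient library of each replicate number, and median log2 changes were 0.84 for morning and -0.36 for evening genes, with 0 limma calls in either (0 and 3 at an unadjusted p below 0.05).

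**Figure D2:**
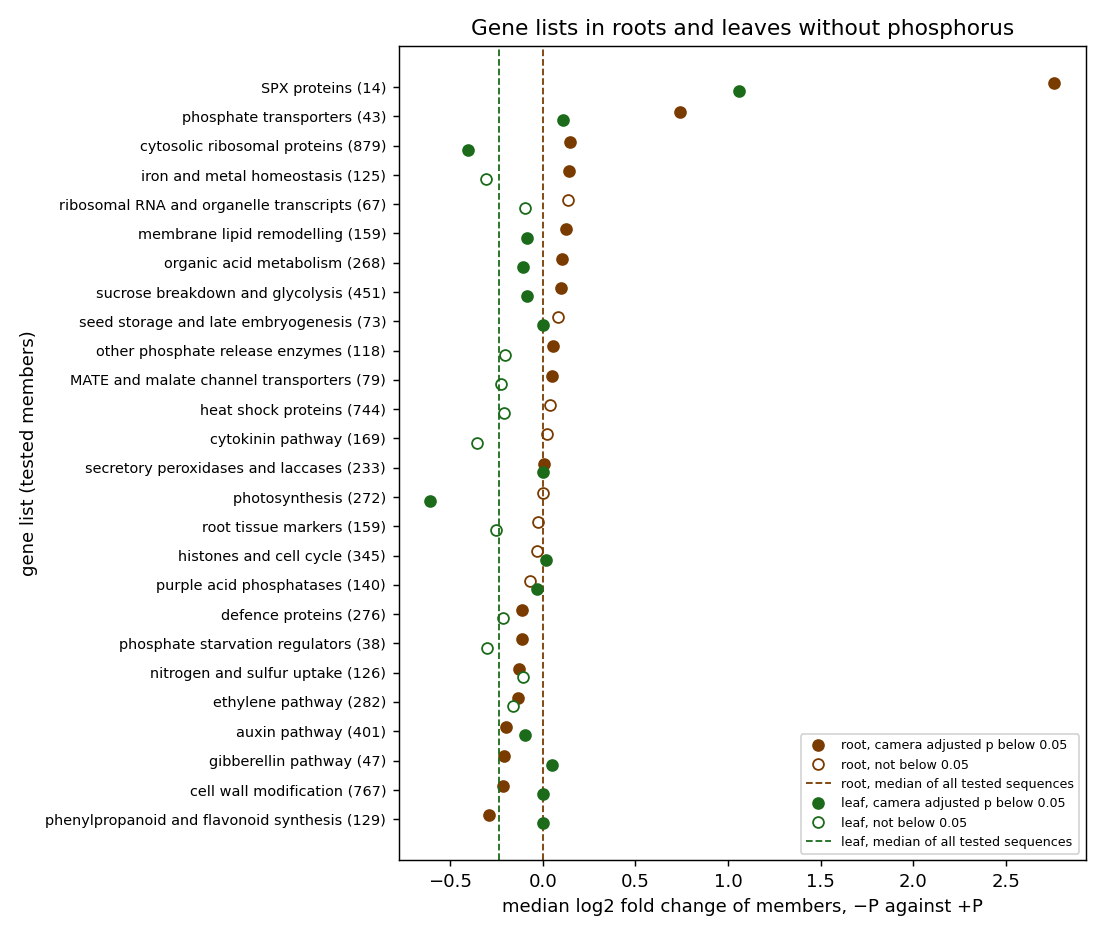
Median log2 change with phosphorus deficiency of the 26 tested gene lists in roots and leaves; filled points have a camera adjusted p below 0.05 with the preset correlation, and dashed lines mark the median of all tested sequences (0 in roots, -0.24 in leaves). SPX proteins had the highest median in both tissues, 2.76 in roots and 1.06 in leaves. With the adapted pattern of 31 SPX sequences, not drawn, the median was 0.09 in roots and 0.09 in leaves.

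The leaf comparison asks which transcripts differ between leaves of deficient and sufficient plants. PAP17 (LAGI01_79787), a purple acid phosphatase induced by phosphate starvation in Arabidopsis, rose from 0.90 ± 0.44 to 14.97 ± 13.23 RPKM (n = 3; log2 3.16, SE 0.514, limma adjusted p = 0.0449). It was the only named sequence that rose, since the other 8 that rose have no informative description. A DNAJ co-chaperone (LAGI01_52852) fell from 20.43 ± 14.6 to 0.83 ± 0.67 RPKM (log2 -3.68 ± 0.595, limma adjusted p = 0.0449). The heat stress transcription factor AT-HSFA3 (LAGI01_13765) fell from 11.13 ± 8.06 to 0.40 ± 0.17 RPKM (-3.38 ± 0.497) and the cytokinin response regulator ARR9 (LAGI01_59027) from 16.93 ± 7.24 to 1.97 ± 1.1 RPKM (-2.82 ± 0.42), with limma adjusted p of 0.0348 and 0.0355. The terpene synthase TPS14 (LAGI01_73631) fell from 7.1 ± 1.04 to 1.17 ± 0.68 RPKM (-2.28 ± 0.362, limma adjusted p = 0.0403).

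Falls also passed for a MATE efflux protein (LAGI01_78131, -3.41 ± 0.469, limma adjusted p = 0.0206), a leucine-rich repeat protein (LAGI01_20611, 84.9 ± 43.43 to 9.47 ± 5.73 RPKM, -3.10 ± 0.502, 0.0449) and a sequence described by a pseudo-etiolation phenotype in light (LAGI01_71364, -2.96 ± 0.464, 0.0384). In the deficient leaf libraries the clock gene difference was above each sufficient library (1.58 to 3.08 against -2.65 to 1.45). With it as a covariate, each of these leaf calls was lost (limma adjusted p from 0.48 to 0.762). All 24 leaf calls kept their sign, and their median absolute log2 change went from 3.18 to 2.32. PAP17 stood at 3.11 and TPS14 at -2.56 in that fit, and the DNAJ protein LAGI01_52852 and AT-HSFA3 at -2.31 and -1.81. The clock gene difference also follows supply, so the lost calls alone do not show an effect of the clock.

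SPX proteins had the highest median change in leaves, 1.06, with 0 of 14 called by limma over all sequences (7 higher adjusted over the list alone; camera adjusted p = 4.11e-18, adjusted p = 0.512 with an estimated correlation). The adapted SPX pattern of 31 sequences had a median of 0.09 (6 higher adjusted over the list alone, camera adjusted p = 6.17e-09, adjusted p = 0.924 with an estimated correlation). SPX3 (LAGI01_46560) was at 0.23 ± 0.32 and 4.17 ± 5.2 RPKM (log2 2.06 ± 0.61, limma adjusted p = 0.32), and SPX2 (LAGI01_55123) at 1.3 ± 0.95 and 8.6 ± 8.85 RPKM (1.97 ± 0.591, 0.328; 0.0332 with the block within each tissue). PAP3 (LAGI01_34342) stood at 3.11 ± 0.6 (limma adjusted p = 0.0859), and at 0.0339 with the replicate block. The galactolipid synthase MGD2 (LAGI01_25059) stood at 2.33 ± 0.619 (0.264; 0.0356 with the block within each tissue). ATPT2 (LAGI01_14440 and LAGI01_20605) stood at 1.41 ± 0.376 and 1.26 ± 0.339 (limma adjusted p of 0.265 and 0.266), and PHR1 (LAGI01_13275), the transcription factor of the phosphate starvation response, at -1.24 ± 0.4 (0.388). The remaining core members did not pass either: a ribonuclease T2 (LAGI01_70978, 1.96, limma adjusted p = 0.324), a further MGD2 (LAGI01_19742, 1.49, 0.266) and PHR1 (LAGI01_70874, -0.81, 0.537), the kinase PPCK1 (LAGI01_14415, 1.23, 0.419) and the malic enzyme NADP-ME4 (0.93, 0.564).

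The median of all tested sequences was -0.24 in the leaf contrast, so list medians are read against it. Camera placed higher the phosphate transporters (43 members, 0 called, 2 higher adjusted over the list alone, median 0.11, adjusted p = 5.17e-06), purple acid phosphatases (140, 1 higher, 5 adjusted over the list alone, -0.03, 0.00192; adapted pattern 58, 1 higher, 4.36e-05) and membrane lipid remodelling (159, 0 called, -0.09 with a mean of 0.12, 3.56e-07). Organic acid metabolism (268, 0 called, -0.11, camera adjusted p = 0.00308) and sucrose breakdown and glycolysis (451, 0 called, -0.09, 0.00231) were also placed higher. The last 4 medians, negative here, were 0.22, 0.15, 0.11 and 0.15 with median-of-ratios scaling. All of these lists were at adjusted p = 0.924 with an estimated correlation. Other phosphate release enzymes (118) held 1 called sequence, PAP17 (1 adjusted over the list alone), at camera adjusted p = 0.0531, and 0.0431 with the replicate block (adjusted p = 0.924 with an estimated correlation). The adapted pattern, with 0 of 71 called, was placed higher (camera adjusted p = 0.0032, adjusted p = 0.924 with an estimated correlation). Among MATE and malate channel transporters 2 of 79 fell, LAGI01_78131 and LAGI01_49318 (-3.16 ± 0.482, limma adjusted p = 0.0384), and 6 were lower adjusted over the list alone (camera adjusted p = 0.272). The phosphate starvation regulators had 0 of 38 called (camera adjusted p = 0.546).

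Photosynthesis had 0 of 272 sequences called in leaves and a median of -0.61, or -0.30 with median-of-ratios scaling (camera adjusted p = 0.00308, adjusted p = 0.924 with an estimated correlation). The adapted photosynthesis pattern of 179 sequences had a median of -0.74 (camera adjusted p = 2.27e-07, adjusted p = 0.924 with an estimated correlation). Cytosolic ribosomal proteins were placed lower (879, 0 called, median -0.40, camera adjusted p = 0.0199), a call lost with median-of-ratios scaling (0.305). This list was at adjusted p = 0.924 with an estimated correlation. Placed higher with 0 called were histones and cell cycle (345, median 0.01, camera adjusted p = 1.53e-08), cell wall modification (767, 0, 1.09e-05), secretory peroxidases and laccases (233, 0, 1.32e-04) and seed storage and late embryogenesis (73, 0, 0.00213; 2 lower adjusted over the list alone). So were phenylpropanoid and flavonoid synthesis (129, 0, 0.00368), the auxin pathway (401, -0.10 but 0.075 with median-of-ratios scaling, 0.0245; 2 lower adjusted over the list alone) and the gibberellin pathway (47, median 0.05, mean -0.17, 0.0199; 1 higher and 7 lower adjusted over the list alone). The means of the 4 lists with a median of 0 were -0.025, -0.066, -0.06 and -0.078 in the order given. Each of these lists was at adjusted p = 0.924 with an estimated correlation, and the gibberellin call was lost with median-of-ratios scaling (0.127). Heat shock proteins had 3 of 744 lower, all DNAJ proteins (5 adjusted over the list alone, camera adjusted p = 0.608). The cytokinin pathway had 1 of 169 lower, ARR9 (3 adjusted over the list alone), at camera adjusted p = 0.0698 and 0.0195 with median-of-ratios scaling (adjusted p = 0.924 with an estimated correlation). Defence proteins (276, 0 called, 8 lower adjusted over the list alone, 0.654), iron and metal homeostasis (125, 0.608), nitrogen and sulfur uptake (126, 0.0926), the ethylene pathway (282, 0.155), root tissue markers (159, 0.607) and ribosomal RNA and organelle transcripts (67, 0.0943) did not pass camera. Deficient replicate 3, with 70.91% of its RPKM in 20 sequences, and the clock gene difference bear on all of these groups.

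**Figure D3:**
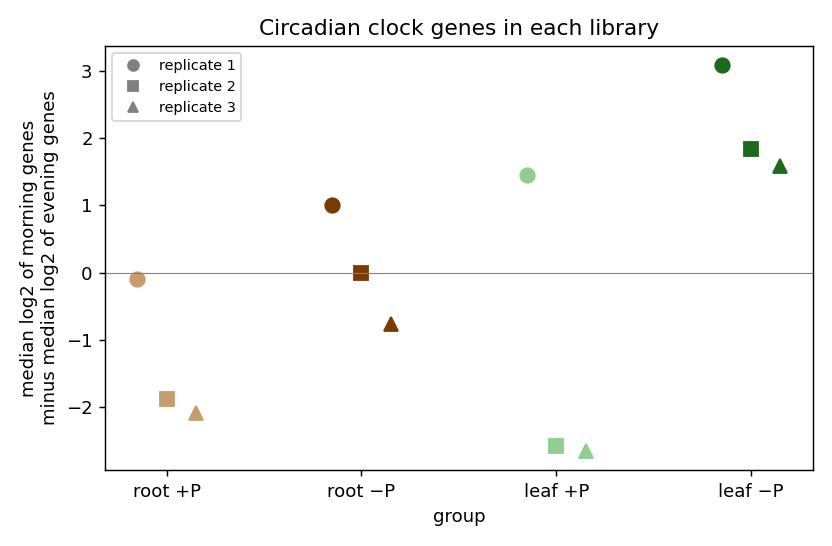
Median log2(RPKM + 0.5) of morning clock genes minus that of evening clock genes in each of the 12 libraries, by group; symbols are replicates 1 to 3. Sufficient leaf libraries span 4.1, from -2.65 to 1.45, and deficient leaf libraries lie between 1.58 and 3.08.

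In all, limma called 24 sequences in the leaf phosphorus response, 9 higher and 15 lower, all changed at least 2-fold (6754 at an unadjusted p below 0.05). The split was 13 and 41 with median-of-ratios scaling and 14 and 38 with quantile normalization. The 8 leaf calls named first were kept in 12 to 18 of 26 alternatives. The count rests on few libraries: it was 0 without deficient replicate 3 (leaf), 2 without sufficient replicate 2 or 3, 1487 without sufficient replicate 1 and 543 without deficient replicate 1. The barcoded libraries alone gave 5215 calls (632 higher, 4583 lower), and with median-of-ratios scaling 5758 higher and 8650 lower. The replicate block gave 158 calls and the block within each tissue 253, while the clock gene covariate gave 0. Morning clock genes had a median change of 1.78 and evening clock genes of -1.49 in leaves, with 0 limma calls in either and 29 of 35 and 32 of 40 sequences at an unadjusted p below 0.05.

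Between the tissues, 4 sequences rose in both, none with an informative description: LAGI01_71501, LAGI01_66113, LAGI01_63011 and LAGI01_56368, named after their values were seen. They changed by 4.61, 4.18, 4.70 and 4.22 in roots and by 3.86, 3.72, 4.65 and 3.89 in leaves on the log2 scale. Independent lists would share 0.022 sequences (one-sided Fisher's exact test, p = 4.34e-09). The test takes sequences as independent, which copies and isoforms are not, so this p can be too small. Root and leaf calls of a sequence also rest on the same estimate of its spread, so the lists are not fully independent. No sequence fell in both (0 shared, 0.00517 for independent lists, one-sided Fisher's exact test, p = 1). Across all 87081 sequences, which are not independent replicates, the changes of the tissues correlated at -0.005, and at 0.322 over the 243 called in roots (46.5% with the same sign).

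The test of the difference of the phosphorus response between root and leaf found 52 sequences, 51 of them more positive in roots and 1 in leaves (5160 at an unadjusted p below 0.05). With median-of-ratios scaling the split was 55 and 14 and with quantile normalization 64 and 10 (median over all sequences 0.27). The largest differences were those of PAP10 (LAGI01_35427, 5.96 ± 0.512 SE, limma adjusted p = 4.24e-05), the putative nodulin (LAGI01_56202, 5.02 ± 0.625, 0.00159), PHT5 (LAGI01_79525, 4.92 ± 0.561, 7.23e-04), the putative peroxidase (LAGI01_45494, 4.66 ± 0.412, 4.46e-05) and FRD3 (LAGI01_21605, 4.57 ± 0.788, 0.0436). The nodulin and PHT5 were listed at 0 in all 6 leaf libraries and PAP10 in the 3 sufficient ones. The sequence more positive in leaves, LAGI01_72026, has no informative description and was named after its values were seen (-4.07, limma adjusted p = 0.0457). PAP17, called in leaves, did not differ between tissues by this test (limma adjusted p = 0.871). The barcoded libraries alone gave 1559 calls, the block within each tissue 84, and the FRD3 difference was kept in 12 of 24 alternatives.

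Root and leaf were compared at each supply to give the tissue background. With sufficient phosphorus, transcripts of photosynthesis were far lower in roots: the RuBisCO small subunit RBCS-2B (LAGI01_69646) stood at 0.27 ± 0.21 against 29810.73 ± 7713.45 RPKM in leaves (log2 -15.25 ± 0.717 SE, limma adjusted p = 2.64e-10). RBCS-1B (LAGI01_65894) stood at -13.48, ferredoxin FED A (LAGI01_72487) at -12.64, and the photosystem I proteins PSAG (LAGI01_90086) and LHCA4 (LAGI01_60095) at -11.95 and -11.48. Higher in roots were a lipid transfer protein (LAGI01_58509, 788.8 ± 579.52 against 0.33 ± 0.32 RPKM, 9.72 ± 0.532, limma adjusted p = 8.99e-10) and a quinone reductase (LAGI01_75000, 9.71). So were an early nodulin-related protein (LAGI01_71342, 9.68), the alpha-dioxygenase DOX1 (LAGI01_84764, 9.41) and the osmotin ATOSM34 (LAGI01_47843, 9.34). Of 272 photosynthesis sequences 199 were lower and 32 higher in roots (201 and 35 adjusted over the list alone), with a median of -4.06 (camera adjusted p = 1.52e-31, adjusted p = 0.418 with an estimated correlation). Without sequences such as plastocyanin-like proteins, the adapted pattern had 166 of 179 lower and 3 higher (169 and 3 adjusted over the list alone, median -5.96, camera adjusted p = 1.25e-60, adjusted p = 0.128 with an estimated correlation). Phosphate transporters were higher in 38 of 43 (38 adjusted over the list alone, median 2.65, camera adjusted p = 8.78e-15). Secretory peroxidases and laccases were higher in 156 of 233, with 9 lower (164 and 10 adjusted over the list alone, median 2.28, camera adjusted p = 9.15e-20). Both lists were at adjusted p = 0.296 with an estimated correlation. Phenylpropanoid and flavonoid synthesis was higher in 92 of 129 and lower in 18 (94 and 19 adjusted over the list alone, camera adjusted p = 4.56e-07, adjusted p = 0.956 with an estimated correlation). Root tissue markers had 29 of 159 higher and 9 lower (26 and 9 adjusted over the list alone) and did not pass camera (adjusted p = 0.102).

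With deficient phosphorus the same photosynthesis proteins led the transcripts lower in roots: RBCS-2B at -13.36, RBCS-1B at -11.78, FED A at -11.19 and PSAG at -10.47 (limma adjusted p from 2.73e-10 to 8.36e-10), with the lipid transfer protein LTP4 (LAGI01_92002) at -10.60. Higher in roots were a quinone reductase (LAGI01_55791, 681.87 ± 70.26 against 0.13 ± 0.15 RPKM, log2 10.10 ± 0.368, limma adjusted p = 1.41e-10) and the lipid transfer protein LAGI01_58509 (9.63). ATOSM34 (9.40) and a lectin protein kinase (LAGI01_70412, 9.10) were higher too. The quinone reductase FQR1 (LAGI01_76787) stood at 275.4 ± 55.31 RPKM in roots and was listed at 0 in the 3 leaf libraries. Photosynthesis had 189 of 272 lower and 35 higher (191 and 37 adjusted over the list alone, median -3.49, camera adjusted p = 4.66e-39, adjusted p = 0.276 with an estimated correlation). The adapted pattern had 160 of 179 lower and 3 higher (163 and 3 adjusted over the list alone, median -5.18, camera adjusted p = 4.61e-71, adjusted p = 0.0725 with an estimated correlation). Phosphate transporters were higher in 41 of 43 (41 adjusted over the list alone, median 3.41, camera adjusted p = 3.36e-17). Secretory peroxidases and laccases were higher in 152 of 233, with 8 lower (157 and 8 adjusted over the list alone, median 2.55, camera adjusted p = 2.37e-17). Both lists were at adjusted p = 0.216 with an estimated correlation. For nitrogen and sulfur uptake (67 of 126 higher, 24 lower; 79 and 29 adjusted over the list alone) camera gave adjusted p = 0.0638, and 0.0335 with the replicate block (adjusted p = 0.986 with an estimated correlation).

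Limma called 36541 sequences between tissues with sufficient phosphorus (21029 higher and 15512 lower in roots; 35572 changed at least 2-fold) and 36763 with deficient phosphorus (25274 higher and 11489 lower; 35565 changed at least 2-fold). Of the calls at sufficient supply, 28341 (77.6%) were also called in the same direction at deficient supply and 22 in the opposite direction. The others were not called at deficient supply. The median over all sequences was 0.19 and 0.42, and with median-of-ratios scaling the splits were 22431 and 22002 (root against leaf with phosphorus) and 21899 and 20411 (root against leaf without phosphorus). The barcoded libraries alone gave 37509 and 37167 calls.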

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

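The splits and the contrast for the difference of responses were planned, while median-of-ratios scaling, the block within each tissue, the clock covariate, adapted list patterns and the sorting of the drawn splits by same-numbered libraries were chosen only after the results were seen. The phosphorus response differed between root and leaf for 52 sequences. PAP10 (LAGI01_35427) differed by 5.96 on the log2 scale and a further PAP10 (LAGI01_49867) by 5.29. The putative nodulin differed by 5.02, PHT5 by 4.92, the putative peroxidase by 4.66, FRD3 by 4.57, LPR1 by 4.45 and ALDH11A3 by 4.31. All of these rose in roots and were not called in leaves. The nodulin and PHT5 were listed at 0 in leaves and the peroxidase and LPR1 stood at no more than 0.07 RPKM there, so for these 4 the difference repeats the root change. PAP10 stood at a mean of up to 0.9 RPKM in leaves, FRD3 at 0.83 and ALDH11A3 at 19.7. TPS14 differed by 2.95. It was called in leaves at -2.28 and not called in roots, so the leaf fall makes up most but not all of the difference. The difference was called in each of 24 alternatives for PAP10, PHT5 and the peroxidase, in 22 for the nodulin and in 12 for FRD3.

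Several lists differed in their response between root and leaf by camera with the preset correlation, and all of them were at adjusted p = 0.969 with an estimated correlation. The median difference was 1.51 for SPX proteins (camera adjusted p = 9.04e-06), 0.65 for phosphate transporters (0.00632), 0.36 for MATE and malate channel transporters (9.15e-04), 0.47 for iron and metal homeostasis (7.13e-04), 0.61 for photosynthesis (0.0448) and 0.54 for cytosolic ribosomal proteins (9.59e-04). With the adapted pattern of 31 sequences the SPX list no longer passed (camera adjusted p = 0.818). Lower than other sequences were the phosphate starvation regulators (-0.065, 5.72e-05), cell wall modification (-0.21, 2.57e-07), phenylpropanoid and flavonoid synthesis (-0.24, 8.09e-08), the auxin pathway (-0.115, 1.9e-05), the gibberellin pathway (-0.29, 7.13e-04) and histones and cell cycle (-0.036, 2.63e-05). The same direction came with positive medians for nitrogen and sulfur uptake (0.001, 0.00389), the ethylene pathway (0.082, 0.00349) and seed storage and late embryogenesis (0.012, 0.0116), since the median over all sequences was 0.27. With median-of-ratios scaling these 3 medians were -0.16, -0.12 and -0.23, and the seed storage call was lost (0.0638).

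Other groupings of the same libraries were tested for each comparison. The root response gave 243 calls and the highest other split 91, so 1 of 10 splits gave as many. The split with 91 keeps the 2 replicate 1 libraries together, and the 3 other splits that part all same-numbered libraries gave 0. The leaf response gave 24 calls, and 3 of 10 splits gave as many, with 847 the highest. The split with 847 and another with 577 both follow the sequencing format in part, putting the 2 replicate 1 libraries with a deficient barcoded library. They also follow the clock gene difference in part, joining libraries at 1.45, 3.08 and 1.83 or 1.58. The other side holds those at -2.57 and -2.65 with the remaining deficient library, so these splits do not separate format from the clock genes. The leaf count was 5215 in barcoded libraries alone, 158 with the replicate block and 253 with the block within each tissue (leaf phosphorus response). The 3 other leaf splits that part all same-numbered libraries gave 0. Root against leaf gave 36541 and 36763 calls with highest other splits of 5 and 0, 1 of 10 in each. With 10 splits a share under 0.05 cannot be reached. For the difference of responses, 3 of 100 drawn splits gave as many as 52, the highest other being 77. That split keeps same-numbered libraries together in both tissues. The next, with 70, does so in leaves and groups the roots by their real supply. The drawn splits with 48, 45, 42, 30 and 29 calls also group the roots by their real supply. The counts of these splits can therefore carry the root phosphorus response. Of the 16 drawn splits that part all same-numbered libraries the highest other gave 29, and 16 are too few for a share under 0.05.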

How the results depend on the processing

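Median-of-ratios scaling, array weights, the block within each tissue, the clock covariate and the removal of particular libraries in combination were chosen only after the results were seen, and the other alternatives were planned. The count-based tests were not run because the values are not counts. Alternatives were run for 30 named genes in roots, 21 in leaves, 5 for the difference and 10 in each tissue contrast, and none of these reversed its direction; other genes in the text have no such values. Of 780 pairs of a gene and an alternative in roots 634 were the same, 125 weaker and 21 stronger, and in leaves 395 of 542 were the same, 107 weaker and 40 stronger. For the difference 106 of 120 were the same and 14 weaker, and all 230 pairs of each tissue contrast were the same. Apart from the calls given with their genes and lists, the replicate block changed no other call of these genes or of a list.

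The root phosphorus response of 243 sequences became 432 with quantile normalization, 106 with a pseudocount of 0.1 and 366 with 1. It was 565 with the block within each tissue (all 565 at least 2-fold), 387 with lane format as a covariate, 442 in barcoded libraries only, 58 with values summed per description and 87 with libraries of that tissue only. Median-of-ratios scaling gave 402, and 397 for the root phosphorus response, changed at least 2-fold. Array weights gave 12564 and that scaling with barcoded libraries 1008. Leaving out 1 library gave 113 to 347, with 113 without sufficient root replicate 2, 120 without sufficient 3, 144 without deficient 2 and 129 without deficient 3. The cause was not tested.

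The leaf phosphorus response of 24 sequences became 52 with quantile normalization, 3 without the filter and 3 with a pseudocount of 0.1. It was 158 with the replicate block (158 at least 2-fold), 253 with the block within each tissue (253 at least 2-fold), and 332 with lane format as a covariate. It was 5215 in barcoded libraries only, 11 with values summed and 781 with libraries of that tissue only. Median-of-ratios scaling gave 54 (54 at least 2-fold), and array weights 2788. That scaling with barcoded libraries gave 14408, that scaling without deficient leaf replicate 3 gave 1, and the clock gene covariate 0. Leaving out 1 library gave 0 to 1487: 7 without sufficient root 2 or deficient root 2, 79 without deficient root 1, 1487 without sufficient leaf 1, 2 without sufficient leaf 2 or 3, 543 without deficient leaf 1, 8 without deficient leaf 2 and 0 without deficient leaf 3. The cause was not tested.

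The difference of the phosphorus response between root and leaf, 52 sequences, became 19 with a pseudocount of 0.1, 84 with the block within each tissue (84 at least 2-fold), and 100 with lane format. It was 1559 in barcoded libraries only, 6 with values summed, 7106 with array weights and 9112 with median-of-ratios scaling in barcoded libraries. Leaving out 1 library gave 28 to 268: 33 and 32 without sufficient root 1 and 3, 28 and 32 without deficient root 2 and 3, 268, 31 and 28 without sufficient leaf 1, 2 and 3, and 176, 31 and 32 without deficient leaf 1, 2 and 3. The cause was not tested.

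The count of root against leaf with phosphorus became 13653 with values summed and 66349 with array weights, and 29419 to 43486 with 1 library left out. That of root against leaf without phosphorus became 13062 with values summed and 28176 to 37194 with 1 library left out. With median-of-ratios scaling in barcoded libraries, overlap of root and leaf phosphorus responses, higher, went from 4 (0.022 for independent lists) to 156 (44.4, one-sided Fisher's exact test, p = 7.33e-44). The overlap of root and leaf phosphorus responses, lower, went from 0 (0.00517) to 51 (33.5, one-sided Fisher's exact test, p = 0.00166). Both overlap tests take sequences as independent, which copies and isoforms are not. They also take root and leaf calls as independent, although both rest on the same estimate of the spread of each sequence. The cause was not tested.

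Of 26 gene lists camera called 18 in the root phosphorus response, 1 with an estimated correlation, 8 with values summed and 2 with fry, which asks another question, since it tests a list against no change and camera tests it against all other sequences. In the leaf phosphorus response 15 became 0, 6 and 0 in the same order. For the difference of the phosphorus response between root and leaf 15 became 0, 3 and 0. For root against leaf with phosphorus 15 became 0 with an estimated correlation, 6 with values summed and 13 with fry, and for root against leaf without phosphorus 12 became 0, 5 and 18.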

Other observations

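The description counts, the MapMan classes, all tests of the deficient leaf library, the format tests and the label tests below were chosen only after the results were seen. Several descriptions had more than 1 sequence that rose in deficient roots; sequences of the same description can be copies or isoforms. Of 12 sequences for NF-YA2, a subunit of a transcription factor, 10 rose (log2 1.61 to 2.00), as did 7 of 7 for formamidase (3.44 to 3.88) and 4 of 4 for malate synthase MLS (3.03 to 3.57), an enzyme of the glyoxylate cycle. Of transcription factors of iron uptake, 4 of 8 FRU sequences (1.95 to 2.32) and 2 of 4 for BHLH038 (4.03 to 4.08) rose, as did a further sequence similar to the same factor and described as FIT1 (LAGI01_33645, 3.93, limma adjusted p = 0.0034). The other FRU and BHLH038 sequences did not pass, and no list of such factors was tested. The potassium transporter ATKT1 (2 of 8, 3.26 to 3.40) and the proton pump AHA2 (2 of 18, 2.15 to 2.36) rose too.

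By MapMan class, metal acquisition was higher in deficient roots (8 of 26 called, median 0.51, camera adjusted p = 9.49e-24), as was mitochondrial electron transport (423 members, 0 called, 0.42, 5.21e-13). Cellulose synthesis (233, -0.37, 1.43e-11), jasmonate (148, -0.41, 7.72e-11) and sugar transporters (277, -0.22, 1.06e-08) were lower. In leaves the light reactions of photosynthesis were lower (303, -0.66, 2.83e-07). The root classes were at adjusted p = 1 with an estimated correlation and the leaf class at 0.994.

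The deficient leaf library of replicate 3 differed from its group by a median log2 ratio of -1.29. Divided by the sum left without its 20 largest sequences the ratio was -0.19 (SD 0.61, 25419 sequences), so most of the shift may come from those sequences. Of these 20, 3 have an informative description (CAB1 and a pair of RuBisCO small subunits), and these 3 were lower here than in each other leaf library. CAB1 stood at 7145.6 RPKM against 18533.3 to 32619.7, and RBCS-2B at 6565.5 against 20515.4 to 38688.1. The excess therefore lies in sequences without an informative description. The 20 sequences held 2.32% to 13.06% in other libraries, and the largest, without such a description, stood at 133862.3 RPKM against at most 9910.3. Lower depth would raise the commonest low value, whose ratio to the highest other library was 1. Phosphorus supply would act on its whole group, but in deficient replicate 2 the library's own 20 largest sequences held 12.51%.

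The root replicate 1 libraries leaned toward leaf, with mean correlations of 0.437 and 0.482 with leaf libraries against 0.308 and 0.331 for the other replicates. The 77 and 348 sequences raised at least 4-fold in these libraries, with a leaf mean of at least 5 RPKM, would need a median leaf RNA share of 138.85% and 126.27%. They were picked for their rise, which lifts the share needed. The most abundant photosynthesis sequences allowed at most 1.23% of leaf RNA. What share the higher correlations would need was not tested. A length bias was small, as judged by the sequence number, which was taken to follow length (Spearman rho -0.163 and -0.156). A shared effect of format was not seen in 1 of 4 pairings (0.022, with the others at 0.34, 0.101 and 0.281). The pairings at 0.022 and 0.101 use deficient leaf replicate 1, whose deviation is from a mean that includes the outlying deficient replicate 3. A shared effect of format is therefore not excluded. These libraries had the highest morning minus evening clock difference of their groups (-0.09 and 1.0), and the cause remains open.

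Leaf libraries grouped by something other than phosphorus, since another split gave 847 calls against 24; sequencing format stays open, because that split raised the question and cannot also test it, and lane format as a covariate gave 332 (leaf phosphorus response). Time of harvest in the day may contribute, as the clock difference spanned 4.1 within sufficient leaves, and with it as a covariate 0 leaf calls remained, though all 24 kept their sign and the median absolute log2 change went from 3.18 to 2.32; it also follows supply, whose effect on the clock stays open. For a wrong label of deficient replicate 1, the SPX median of 1.14 lay below the 1.43 of sufficient replicate 2, which goes with a wrong label, but within each replicate number the deficient library was higher (1.14 against 0.2, 3.48 against 1.43 and 1.87 against 0.88), which goes against it. A second test, chosen after that result and tried 6 ways, found 59.0% of 39 descriptions above each sufficient leaf library (exact binomial interval 42.1 to 74.4). Chance gives 25%, and the 6 ways gave 53.5% to 83.3%, which also leans against a wrong label. However, sufficient replicate 2 exceeded its own chance share of 33.3% when sequences were counted (46.5%, exact binomial interval 34.5 to 58.7). With descriptions it stood at 38.5% (23.4 to 55.4), and sufficient replicates 1 and 3 at 30.8% and 17.9%. The chance share is therefore a weak benchmark. Most values of deficient replicate 1 go against a wrong label, but they concern 1 library and genes are not independent. The comparisons within replicate numbers and of descriptions were also chosen afterwards, so the question stays open.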
